A study of Mus musculus with 127 samples.

How the data were processed

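The series holds 127 single mouse cells of strain C57BL/6 from 4 embryonic sources: 32 from the aorta with the umbilical and vitelline arteries (AUV), 28 from the yolk sac (YS), 36 from the placenta (PL) and 31 from the fetal liver (FL). Per the labels' protocols, dissected tissue was digested with collagenase and Dispase, cells were enriched by flow cytometry, and libraries were made on the Fluidigm C1 system with the SMARTer Ultra Low RNA kit, a full-length method without molecular identifiers. The titles of the fetal liver cells name a sort called LSK-SLAM. The gates of the other tissues are not given in the sources used here.

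The authors deposited a table of estimated counts per gene and cell, with 30992 rows, and a sample table with a group number from 1 to 3 for each cell. Per the submitters' processing notes, cutadapt, Salmon and HISAT2 were used with builds GRCm38 and GRCh38, with no versions or roles given. The estimated counts are not normalised, and 63.0% of the values above 0 lie more than 0.001 from a whole number. Such fractions arise where reads are divided among similar sequences, so values of genes with near-identical copies, such as Hbb-bs and Hbb-bt or Hba-a1 and Hba-a2, are uncertain. The kit marks no strand, so reads of overlapping and antisense genes cannot be separated. The 104 rows that name no mouse gene (spike-in controls, reporter and selection sequences) were kept out of library sizes. They held a median of 0.0198% of a cell's counts and at most 0.154%.

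Each GEO sample is 1 cell, and the labels name no embryo, litter or culture. Each tissue was therefore treated as 1 sample, and no test, p-value or standard error was computed from cells. SDs given below describe the spread over cells. Intervals on shares are exact binomial (Clopper-Pearson) and those on summed counts exact Poisson, both at 95%. They cover counting error only, and since reads without molecular identifiers are not independent molecules, the Poisson intervals are too narrow even for that. A count of 0 was read against a limit of 3 counts.

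Counts were divided by the cell's total over genes and scaled to CPM, in which every cell has the same total. Cells needed at least 50000 counts and 1000 genes with a read, which removed 0 cells. A read means an estimated count of at least 1. Each comparison used the log2 ratio of mean CPM over cells with a pseudocount of 1 CPM, and fold values are of these means plus 1 CPM. The 4 comparisons were AUV with YS, PL with FL, AUV with FL and YS with PL. The sample descriptions begin with a library identifier, here called the pool, which AUV shares with YS and PL with FL. In AUV with FL and YS with PL, pool and tissue cannot be told apart. Within a pool each tissue holds its own run of sample numbers, so preparation and tissue may coincide there too.

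Before the data were examined, 26 gene lists, markers of 11 cell classes, the comparisons, most of the alternatives and the rule for named genes were fixed. For a list, the median log2 ratio over members with a mean of at least 1 CPM was set against 10000 random lists of the same size, matched on mean expression in 20 bins. Its percentile describes these libraries and is no test. Lists with fewer than 3 such members were left out. The rule named, per comparison and direction, the 12 genes with the largest difference of mean log2(CPM + 1) among genes with a read in at least 50% of the cells of the higher tissue, a mean of at least 20 CPM there and a log2 ratio of at least 1. Predicted genes, clone names, mitochondrially encoded genes, ribosomal protein genes and pseudogenes by name were left out. Within a class the rule took 6 genes per direction. Members of the lists, Runx1, Ly6a, Xist and 4 Y-linked genes could be named as well.

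Cells were clustered on log2(CPM + 1) of the 2000 most variable genes with 15 principal components, 10 neighbours and Leiden resolution 1 (scanpy 1.11.5, igraph 0.11.9). No cluster had more than 1 marker of any class among its top 10 genes, so all clusters stayed unnamed, and levels within a class were compared within the authors' deposited groups. No doublet caller was run on 127 cells. The highest correlation of log2(CPM + 1) between 2 cells was 0.818, and no libraries were merged.

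Alternatives were a pseudocount of 5 CPM, summed counts, scran size factors (scran 1.30.0 in R 4.3.3, on counts rounded to whole numbers), no filter on cells, a filter of 200000 counts and 2000 genes (1 cell removed), a 10% trimmed mean, a denominator without mitochondrial, haemoglobin and ribosomal protein genes, thinning to 100000 counts (1 placental cell too shallow), other floors for list members, detection at 10 CPM and other clustering settings. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Random lists were also drawn anew under each alternative, and levels of genes were averaged again without the cell with most of the gene, steps added after seeing the data. The calculation was tested on simulated PL and FL cells with 200 altered genes among 12857 in the step. The 100 genes altered by a log2 ratio of 1 came out at a median of 0.91, and the 100 altered by 2 at 1.93. Of 200 simulated lists of unaltered genes, 5.5% fell outside the central 95% of random lists. Simulated genes varied independently and list members were drawn at random, whereas genes of the fixed lists can vary together or rest on single cells. The 5.5% therefore does not tell how often such lists fall outside without a tissue difference. Gene positions are from GENCODE M21 on GRCm38, matched by symbol.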

Results

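The data are full-length RNA profiles of 127 single cells from 4 sites of blood formation in the mouse embryo, collected, per the series' title and design text, to follow transcription during haematopoietic stem cell formation with a combined Runx1 and Ly6a reporter. Runx1 is the transcription factor required for blood to form from endothelium, and Ly6a encodes Sca-1, a surface marker of stem cells. AUV gave 32 cells, YS 28, PL 36 and FL 31. Estimated counts per cell ran from 73786 to 7936875, with a median of 1856351. Median depths were 1977263 in AUV, 2444231 in YS, 1641806 in PL and 1548748 in FL. The median number of genes with a read was 10449 in AUV, 10003 in YS, 8058 in PL and 7375 in FL. The labels identify no replicates of a tissue, so differences below are between these sets of cells.

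**Figure D1:**
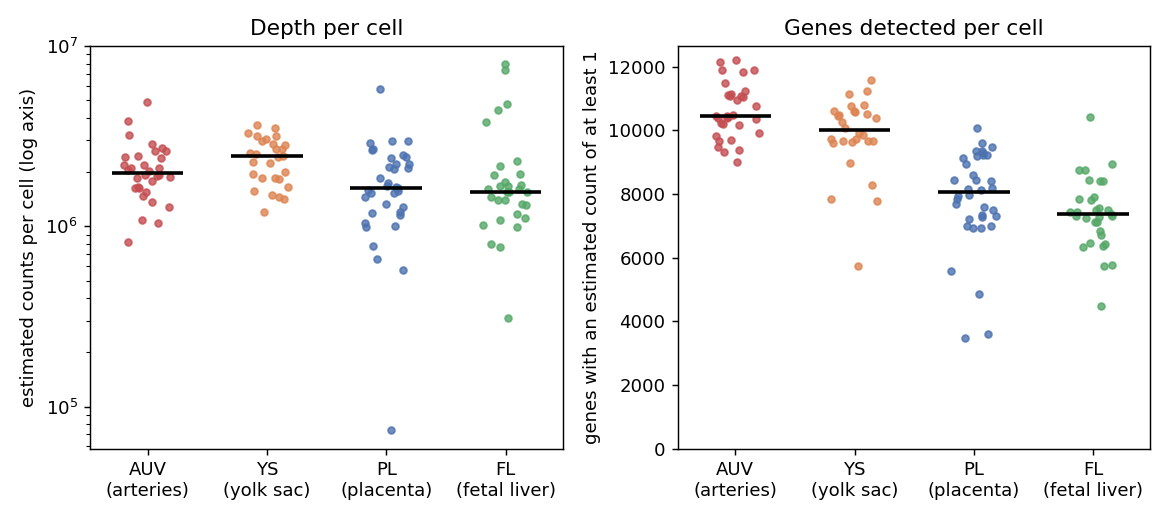
Estimated counts per cell (left, log axis) and genes with an estimated count of at least 1 (right) for the 127 cells, by tissue; each point is a cell and each black bar the median. AUV and YS cells, from one library pool, have medians of 10449 and 10003 genes, above those of PL (8058) and FL (7375).

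A few cells stood apart. Mitochondrially encoded genes took 69.3% of the counts in 1 AUV cell, against a median of 2.79% in AUV. In 1 YS cell they took 0.00198%, and the ribosomal RNA gene Rn18s-rs5 took 17.2%. The placental cell with 73786 counts was the shallowest. Cells with at least 10 CPM of Xist, transcribed from the inactive X, and cells with at least 10 CPM of 4 Y-linked genes occurred in each tissue. Xist reached this level in 24 of 32 AUV, 13 of 28 YS, 15 of 36 PL and 16 of 31 FL cells. The Y-linked sum reached it in 25 AUV, 19 YS, 16 PL and 12 FL cells. The labels assign no cell to an embryo. Over cells, the median share of counts taken by Rn18s-rs5 was 0.918% in AUV, 1.21% in YS, 0.135% in PL and 0.543% in FL.

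The reporter genes and the stem cell genes differed among the sites. Runx1 (chromosome 16, 92601466 to 92826149) had a read in every cell of the 4 tissues with counts as deposited. It reached 10 CPM in 32 of 32 AUV, 26 of 28 YS, 34 of 36 PL and 16 of 31 FL cells. Thinned, it was found in 32 of 32 AUV, 25 of 28 YS, 32 of 35 PL and 22 of 31 FL cells. Its mean was 250.4 CPM in AUV (SD 202 over cells), 222.5 in YS, 148 in PL and 106 in FL (SD 227). Ly6a (chromosome 15, 74994877 to 74998031) averaged 2.09 CPM in AUV, 6.38 in YS, 14.8 in PL and 93.0 in FL, and 1.44, 2.01, 8.38 and 70.6 CPM without the cell of each tissue with most (AUV cell 25, YS cell 18, PL cell 26 and FL cell 23). It had a read in 51.6% of FL cells (33.1 to 69.8%), 25% of AUV cells, 14.3% of YS cells and 25% of PL cells. The LSK-SLAM sort of the fetal liver uses Sca-1, so the gate can set this share. After thinning, Ly6a had a read in 38.7% of FL, 12.5% of AUV, 7.14% of YS and 17.1% of PL cells.

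The H2Bsm-mKO2 sequence had a read in 93.8% of AUV, 89.3% of YS, 88.9% of PL and 87.1% of FL cells. The near-identical YFP and eGFP sequences, counted as one, had a read in 54.8% of FL cells (36 to 72.7%), against 21.9% in AUV, 28.6% in YS and 22.2% in PL. In FL, 13 of 31 cells had reads of both Ly6a and YFP or eGFP, 3 of Ly6a alone, 4 of the fluorescent sequences alone and 11 of neither. The labels do not say which sequence reports which gene.

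Cdh5 (chromosome 8, 104101625 to 104144511), the VE-cadherin gene of endothelium, had a read in 81.2% of AUV cells (63.6 to 92.8%), 57.1% of YS, 47.2% of PL and 41.9% of FL cells. After thinning the shares were 59.4%, 39.3%, 20% and 6.45%. Cdh5 together with Ptprc, which encodes the pan-leukocyte marker CD45, was found in 78.1% of AUV cells (60.0 to 90.7%), 42.9% of YS, 30.6% of PL and 32.3% of FL cells, and after thinning in 59.4%, 21.4%, 8.57% and 3.23%. Xist and Y-linked reads at 10 CPM were found together in 53.1% of AUV, 28.6% of YS, 11.1% of PL and 12.9% of FL cells, and libraries holding reads of more than 1 cell were not excluded for these shares. Itga2b (chromosome 11, 102453297 to 102470122), which encodes the early haematopoietic and megakaryocytic integrin CD41, had a read in 10 of 32 AUV, 7 of 28 YS and 6 of 36 PL cells. After thinning it had a read in 9.38% of AUV, 7.14% of YS and 5.71% of PL cells, all within the FL interval given next. It had 0 reads in FL, where 0 of 31 cells have an exact interval up to 11.2%, and the limit of 3 counts gives a share of up to 9.68%. Mecom, a regulator of stem cell maintenance, had a read in 87.1% of FL, 75% of AUV, 71.4% of YS and 47.2% of PL cells.

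**Figure D2:**
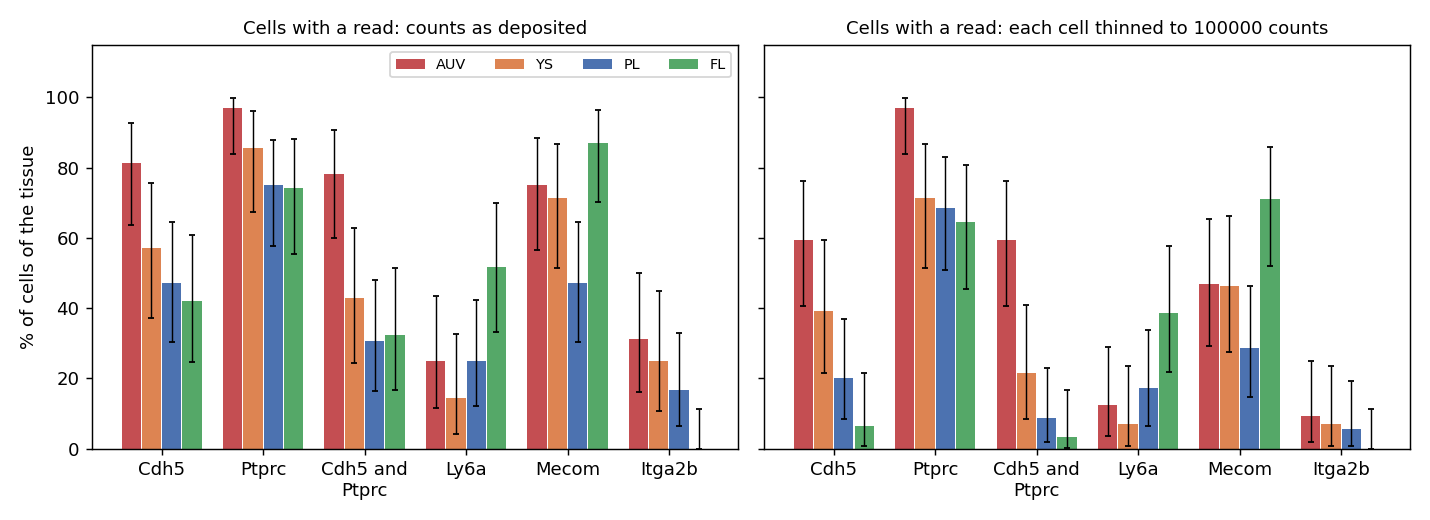
Share of the cells of each tissue with a read of the named genes, with counts as deposited (left) and after thinning each cell to 100000 counts (right); bars are percentages and lines exact binomial 95% intervals, which cover counting error only. Cells with both Cdh5 and Ptprc make up 78.1% of AUV and 32.3% of FL cells as deposited, and 59.4% and 3.23% after thinning.

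The first comparison set arterial cells against yolk sac cells, which shared a library pool. AUV cells had higher levels of stem cell, DNA replication and basement membrane genes than YS cells. Of 21 stem and progenitor genes, 15 were higher in AUV, with a median log2 ratio of 0.54 at percentile 99.9 of random lists. Hoxa9, a homeobox gene of stem cells, averaged 72.1 CPM in AUV and 22.9 in YS, with a read in 29 of 32 and 12 of 28 cells. Hlf, a stem cell transcription factor, averaged 107.5 and 35.6 CPM, the interferon-inducible Ifitm1 385 and 83.9 CPM, and the stem cell factor receptor gene Kit 427 and 224 CPM. Procr and Mecom went the other way, at 37.9 and 119 CPM for Procr and 68.3 and 126.5 CPM for Mecom, and 1 YS cell held 91.2% of the YS signal of Procr. Without that cell, YS cell 27, the YS means were 10.9 CPM for Procr, below AUV, and 84.2 CPM for Mecom.

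Among 18 S phase genes 14 were higher in AUV, at a median of 0.47, at percentile 100 of random lists. The replication helicase gene Mcm6 averaged 519 CPM in AUV and 321 in YS, and Chaf1b 157.5 and 51.95 CPM. G2/M genes did not follow, with 5 of 18 higher in AUV and a median of -0.29 at percentile 2.85. Glycolytic genes had a median of 0.30, with 13 of 16 higher in AUV, among them Pkm at 1988 and 1266 CPM. The glycolysis median lay inside the random range (up to 0.24) without AUV cell 32, at 0.23. Basement membrane genes had a median of 1.27, with 9 of 11 higher in AUV, such as Col18a1 at 146 and 59.1 CPM and Fn1 at 65.6 and 12.2 CPM, or 6.33 without YS cell 13. The list's median was 0.84 without AUV cell 30. All 7 measured erythroid genes were higher in AUV, at a median of 1.62, though most were scarce, with Hbb-bt at 16.7 and 1.14 CPM, or 9.34 in AUV without AUV cell 30 and 0.72 in YS without YS cell 22. Over the 3 members of at least 10 CPM the median was 0.26, inside the random range.

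Cholesterol synthesis genes had a median of -0.38, with 9 of 16 higher in YS. The median lay inside the random range without YS cell 1 (-0.29), with summed counts (-0.35), with trimmed means (-0.28), after thinning (-0.26) and without cells of outlying mitochondrial share (-0.25). Insig1, which restrains sterol synthesis, averaged 30.3 CPM in AUV and 83.8 in YS. Venous and lymphatic genes had a median of -0.94, with 5 of 6 higher in YS, led by Lyve1 at 3.27 and 53.1 CPM, or 12.6 in YS without YS cell 27 and 1.0 in AUV without AUV cell 13. Inside the random range were its values without YS cell 27 (-0.26) and with trimmed means (-0.011). The macrophage list had a median of -0.56 with 6 of 10 higher in YS. It turned to 0.018 without YS cell 21 and to 0.25 over members of at least 10 CPM, was -0.30 and inside the random range after thinning, and the median of its differences in mean log2(CPM + 1) was 0.14, against 0.20 over all genes.

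By the fixed rule, AUV cells were higher in the zinc finger gene Zfp260 (5.36-fold), Serpina3g (4.96-fold), the kinase gene Pak1 (2.06-fold), Maged1 (6.22-fold), Dapp1 (3.05-fold), the keratin gene Krt18 (5.68-fold), Phkb (8.10-fold), Slc43a3 (2.49-fold), Tubgcp2 (9.65-fold), the leukocyte gene Lsp1 (2.29-fold) and the glycophorin gene Gypc (3.40-fold). YS cells were higher in Zfp777 (9.82-fold), Srf, the serum response factor gene (7.78-fold), Clec1b, a platelet and myeloid lectin receptor gene (9.19-fold), Slc33a1 (8.04-fold), Crtc1 (4.07-fold), Id2, an inhibitor of helix-loop-helix factors (3.97-fold), Ints12 (3.22-fold), Dlst (2.63-fold), G6pdx (2.37-fold), Rab5a (2.28-fold) and Arhgap1 (2.07-fold). Without the cell of the lower tissue with most of the gene, 14 of the 24 folds were over 1.5 times larger, at most 3.52 times (Slc33a1). Across the fixed lists, 8 of 25 lay outside the central 95% of random lists.

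**Figure D3:**
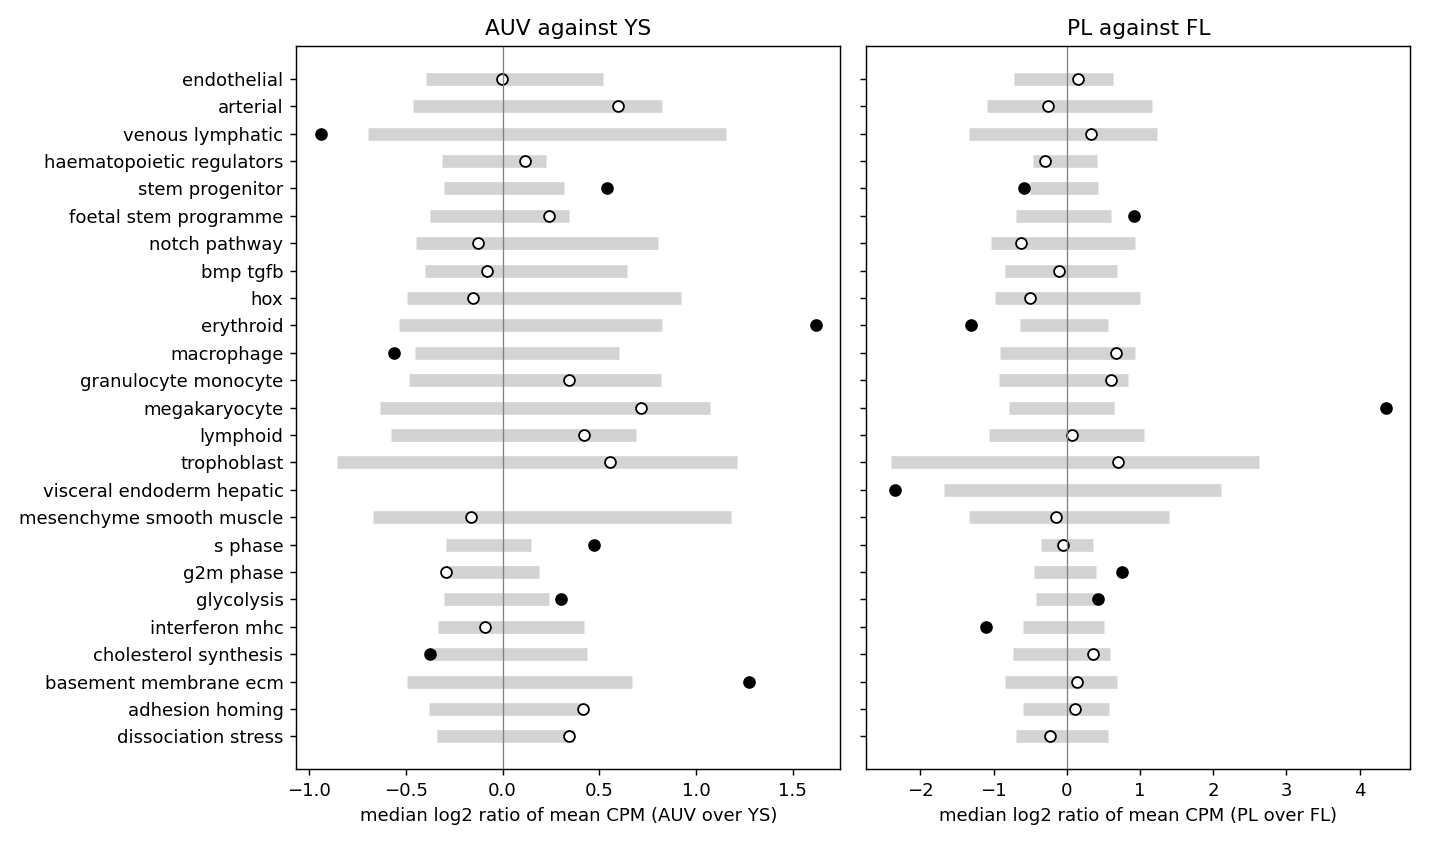
Median log2 ratio of mean CPM over the measured members of each gene list, for AUV over YS (left) and PL over FL (right); grey bars span the central 95% of 10000 random lists matched on expression, and filled points lie outside them. The megakaryocyte list in PL over FL is the farthest right, at 4.36.

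The second comparison set placental cells against the LSK-SLAM cells of the fetal liver, again within a pool. Placental cells had higher levels of mitotic genes, and FL cells higher levels of interferon and antigen presentation genes. Rn18s-rs5 took a median of 0.135% of the counts in PL and 0.543% in FL. Of 18 G2/M genes, 16 were higher in PL, at a median of 0.76 and percentile 99.97. The median was 1.65 with trimmed means and 0.49 with summed counts, and within the authors' group 1 it was 0.34, inside the random range. The cyclin gene Ccnb1 averaged 462.5 CPM in PL and 204 in FL, with a read in 29 of 36 and 17 of 31 cells. Plk1, a mitotic kinase gene, averaged 185 and 57.8 CPM (27.9 without FL cell 10), and Bub1b 219.5 and 56.4 CPM. S phase genes gave a median of -0.06, with 8 of 18 higher in PL.

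Of 10 foetal stem programme genes, 8 were higher in PL, at a median of 0.92. Igf2, the foetal growth factor, averaged 159 and 25.8 CPM, and Arid3a 102 and 13.7 CPM. Inside the random range were the medians without PL cell 13 (0.54) and with trimmed means (0.69), and 1 PL cell held 59.3% of the PL signal of Igf2, which averaged 66.6 CPM without that cell. Glycolytic genes had a median of 0.42, with 10 of 16 higher in PL, at the edge of the random range (0.41), and lay inside it with summed counts (0.26), scran size factors (0.55), trimmed means (0.54), thinning (0.40), without cells of outlying mitochondrial share (0.37) and without PL cell 22 (0.31).

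The interferon and antigen presentation list was higher in FL in 15 of 19 genes, at a median of -1.11 and percentile 0.05, or -0.48 with trimmed means and -0.64 without FL cell 29. The transcription factor gene Irf1 averaged 46.9 CPM in PL and 193 in FL, the immunoproteasome gene Psmb8 40.2 and 153.5 CPM, Ifitm3 217 and 510.0 CPM, and B2m 334 and 491 CPM. Stem and progenitor genes were higher in FL in 15 of 21 cases, at a median of -0.59. The LSK-SLAM gate uses Sca-1, encoded by Ly6a, which is on this list. The gate may therefore set part of this difference, here and in other comparisons with FL. Mecom averaged 42.7 and 182 CPM, Ifitm1 125 and 451 CPM, and Pbx1 59.5 and 162 CPM, while Itga2b averaged 28.9 CPM in PL. Single cells set part of these means: Mecom averaged 26.9 CPM in PL without PL cell 15, Pbx1 104 CPM in FL without FL cell 18, and Itga2b 12.7 CPM in PL without PL cell 11. Without FL cell 18 the stem cell median was -0.40, inside the random range.

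All 12 megakaryocyte genes were higher in PL, at a median of 4.36, and of 3.83 to 4.80 with each cell left out in turn. Reads of at least 6 of these genes were not particular to PL. They occurred in 7 of 36 PL, 6 of 32 AUV, 2 of 28 YS and 1 of 31 FL cells, with counts as deposited. Pf4, a platelet chemokine gene, averaged 1005 CPM in PL and 28.7 in FL, but its median over PL cells was 0.555 CPM. Without PL cell 11 its PL mean was 488 CPM, and without FL cell 17 its FL mean 14.8 CPM. The 2 PL cells with most held 53.3% and 35% of the list's summed CPM. The first of these was PL cell 11, the shallowest of all cells, with 73786 counts and 3467 genes. The list's median was 3.94 with the filter of 200000 counts, which left out that cell, and 2.58 with trimmed means. Erythroid genes had a median of -1.30, which turned to 1.24 without FL cell 1 and was -3.13 without PL cell 14. That median rested on few reads, since 1 FL cell held 99.5% of the FL signal of Gypa. The visceral endoderm and hepatic list, with 3 measured genes, had a median of -2.34 and one of -1.14, inside the random range, without FL cell 28. It also lay inside that range with a pseudocount of 5 CPM (-0.86).

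**Figure D4:**
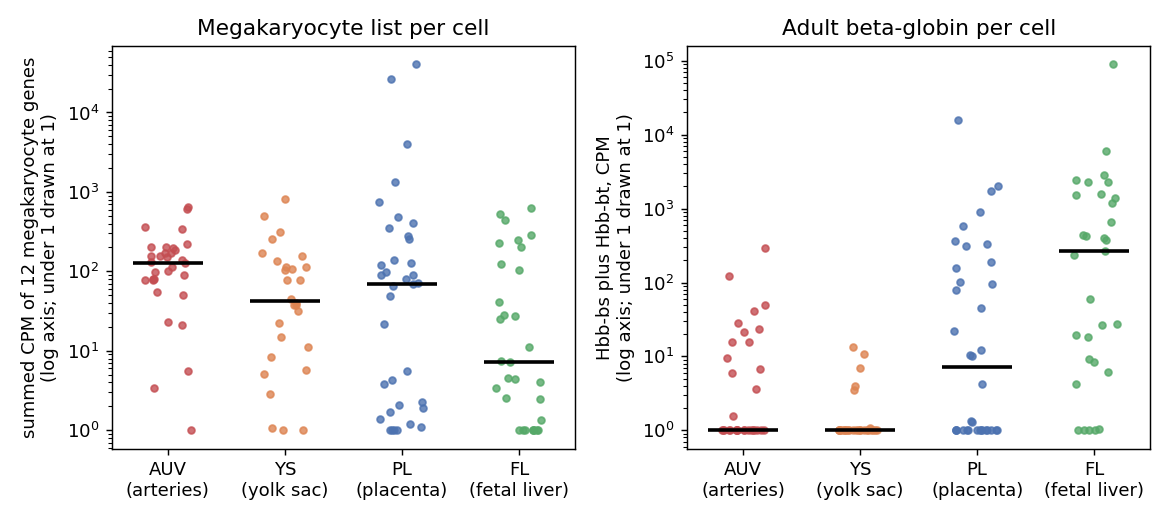
Summed CPM of the 12 megakaryocyte genes (left) and of Hbb-bs plus Hbb-bt (right) in each cell, on log axes with values under 1 drawn at 1; points are cells and black bars medians. The PL median of the megakaryocyte sum is 70 CPM and its mean 2110 CPM, and the FL median of the globin sum is 271 CPM and its mean 3693 CPM.

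Among genes named by the rule, Plek, a pleckstrin gene of platelets and leukocytes, averaged 661 CPM in PL (SD 1398) and 2.47 CPM in FL (SD 5.53), or 1.63 without FL cell 7. Serpinb1a, a leukocyte protease inhibitor gene, averaged 118 and 0.14 CPM, with 10644 counts in PL and 7 in FL (Poisson interval 2.81 to 14.4). The adaptor gene Lims1 was 10.6-fold higher in PL, Tsc22d1 11.2-fold (3.57-fold without PL cell 14), Las1l 9.81-fold, Isyna1 6.82-fold, the cyclin gene Ccnj 5.03-fold, Prmt7 3.72-fold, Mrps27 3.59-fold, Tubb6 3.40-fold, Ociad1 3.39-fold and Sec13 2.44-fold. FL cells were higher in the cholesterol exporter gene Abcg1, at 589 CPM against 90.0, with a read in 31 of 31 FL cells and 34 of 36 PL cells. They were also higher in the interferon-inducible gene Mndal (12.4-fold), the protease gene Ctse (33.3-fold), Ptprcap, whose product binds CD45 (4.43-fold), the imprinted gene Grb10 (5.39-fold), the early response gene Fos (3.58-fold), Lsp1 (2.71-fold) and Lgals1 (2.46-fold). The globin genes Hbb-bt (4.06-fold) and Hbb-bs (14.9-fold) completed the list, at 1.23-fold and 1.65-fold without FL cell 1. Hbb-bs plus Hbb-bt averaged 3693 CPM in FL and 629.5 in PL, 819 in FL without that cell and 199.5 in PL without PL cell 14. With the cell of the lower tissue with most of the gene left out, 12 of the 24 folds were over 1.5 times larger, at most 5.40 times (Tubb6). Of 25 lists, 8 lay outside the random range.

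The third comparison set arterial cells against the LSK-SLAM cells of the fetal liver. The pools differ, so tissue and pool cannot be told apart, and the median gene had a log2 ratio of 0.15, or -0.0045 with pooled size factors. G2/M genes were higher in AUV in 15 of 18 cases, at a median of 0.62, or 1.48 with trimmed means, where the median gene was at 0.72. With summed counts it was 0.25, inside the random range. Interferon and antigen presentation genes were higher in FL in 17 of 19 cases, at a median of -0.84, with Psmb8 at 26.5 CPM in AUV and 153.5 in FL. Glycolytic genes had a median of 0.48, with 13 of 16 higher in AUV, among them Eno1 at 1128 and 458 CPM. It lay inside the random range with summed counts (0.45), with trimmed means (0.68) and without AUV cell 7 (0.42).

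Stem and progenitor genes had a median of -0.63, with 14 of 21 higher in FL, while the median of their differences in mean log2(CPM + 1) was 0.84, close to the 0.82 over all genes. With summed counts the list's median was -0.30, inside the random range. The LSK-SLAM gate, which uses Sca-1, may set part of this list's difference. The endothelial list had a median of -0.80, with 9 of 15 higher in FL. It turned to 0.71 without FL cell 31. With trimmed means it was 1.80, inside the random range of 0.34 to 2.03, and the median gene was at 0.72. It was -0.46 and inside the random range with summed counts, and had a median of mean log2 differences of 0.89, against 0.82 over all genes. Members differed in direction: Cdh5 averaged 69.4 CPM in AUV and 5.82 in FL (1.41 without FL cell 31), whereas Esam, an adhesion gene shared with stem cells, averaged 90.4 and 328 CPM. The venous and lymphatic list behaved likewise, at -1.98, at 0.34 without FL cell 31 and at 0.76 with trimmed means, inside the random range. Erythroid genes were higher in FL in 12 of 14 cases, at a median of -3.74, of -1.18 with trimmed means and of -0.84 without FL cell 1.

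Plek (346 and 2.47 CPM), Serpinb1a (111 and 0.14 CPM) and Lims1 (360 and 32.1 CPM) were higher in AUV than in FL, as they were in PL. So were Lbr, the lamin B receptor gene (6.33-fold), Zfp711 (7.36-fold), Gorasp2 (7.35-fold), Rcbtb2 (6.09-fold), Cyc1 (5.45-fold), Rab14 (5.38-fold), Tsc22d1 (4.05-fold), Tars (3.16-fold) and Tubb6 (3.15-fold). FL cells were higher in Ctse (149-fold), Mndal (34.3-fold), Id3 (21.1-fold, or 12.4-fold without FL cell 21), the cyclin gene Ccnd1 (10.9-fold), the kinase gene Prkaa2 (8.26-fold), Lgals1 (6.77-fold), Cecr6 (6.67-fold), Pou3f2 (6.34-fold), Ptprcap (5.86-fold) and Rgs3 (5.07-fold). Prkaa2, Cecr6 and Pou3f2 had a read in all 32 AUV and all 31 FL cells. For each of them the highest cells were FL cell 26 and AUV cell 31, the cell with 69.3% mitochondrial counts. Whether these reads came from the genes themselves was not tested. Hbb-bt averaged 2143 CPM in FL, or 649 without FL cell 1, and 16.7 in AUV, or 9.34 without AUV cell 30. Leaving out the cell of the lower tissue with most of the gene made 12 of the 24 folds over 1.5 times larger, at most 12.2 times (Zfp711). Of 25 lists, 7 lay outside the random range.

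The fourth comparison set the extraembryonic tissues against each other, yolk sac with placenta, across pools. The median gene had a log2 ratio of 0.14, or -0.06 with pooled size factors. PL cells were higher in megakaryocyte genes (12 of 12, median -3.83), erythroid genes (11 of 11, median -4.93) and granulocyte and monocyte genes (7 of 8, median -0.87). Mpo, the neutrophil peroxidase gene, averaged 351 CPM in YS and 615 in PL, and Prtn3 25.8 (15.4 without YS cell 9) and 50 CPM, while the list's median over members of at least 10 CPM was -0.81, inside the random range. The megakaryocyte median was -1.5 with trimmed means and from -3.98 to -3.16 with each cell left out in turn, and the erythroid median -1.94 without PL cell 14. Within the authors' group 3 (24 YS and 10 PL cells) the megakaryocyte median was -0.55, with 3 of 8 higher in YS and inside the random range, and the erythroid median -1.21, with 2 of 8 higher in YS. Dissociation stress genes were higher in YS in 12 of 15 cases, at a median of 0.62, with Egr1 at 509 and 249 CPM and Btg2 at 223 and 87.7 CPM. It lay inside the random range without YS cell 8 (0.49), with a pseudocount of 5 CPM (0.43), with scran size factors (0.36), with trimmed means (0.77) and with the filter of 200000 counts (0.595).

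Basement membrane genes had a median of -0.95, with 8 of 11 higher in PL, and it was 1.22 with trimmed means, inside the random range of -0.19 to 1.43, where the median gene was at 0.37. The median was -1.48 without YS cell 20, -0.26 without PL cell 13 and -0.55 with summed counts, the last 2 inside the random range, and the median of its mean log2 differences was 0.27, against 0.41 over all genes. The macrophage list was at 0.84. It lay inside the random range without YS cell 22 (0.30) and under 5 of the alternatives, such as summed counts (0.62). Stem and progenitor genes were at -0.40, at -0.63 without YS cell 20 and, without PL cell 1 (-0.27) or with summed counts (-0.25), inside it as well, with a median of mean log2 differences of 0.016. By the rule, YS cells were higher in Zfp655 (4.31-fold), Rnf44 (5.32-fold), Timm50 (5.48-fold), Rcn3 (4.29-fold), Atp13a1 (3.80-fold), Dus1l (3.53-fold), Pdcd6ip (3.11-fold), Kctd12 (2.99-fold), the tropomyosin gene Tpm1 (2.93-fold), the mitochondrial prohibitin gene Phb2 (2.82-fold), Nsun2 (2.75-fold) and Adss (2.57-fold). PL cells were higher in Ncs1 (8.31-fold), Ldhb (5.13-fold), the endothelial receptor gene Adgrl4 (3.98-fold), Cnnm4 (3.82-fold), Tuba4a (3.78-fold, or 2.49-fold without PL cell 11), Bend4 (3.77-fold), the galectin gene Lgals9 (3.27-fold), Lsp1 (3.25-fold), Bscl2 (2.37-fold) and Cd24a (2.04-fold). Hbb-bt (527 against 1.14 CPM) and Hbb-bs (103 against 0.29 CPM) were higher in PL too, at 165 and 34.4 CPM without PL cell 14. In the lower tissue, leaving out the cell with most of the gene made 5 of the 24 folds over 1.5 times larger, at most 3.13 times (Atp13a1). Of 24 lists, 7 lay outside the random range.

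The authors' deposited groups followed tissue, with placenta spread over all 3. Group 3 held 30 of 32 AUV cells, 24 of 28 YS cells and 10 of 36 PL cells, and 0 of 31 FL cells. Group 1 held 29 of 31 FL cells (93.5%, 78.6 to 99.2%), 8 PL cells, 3 YS cells and 1 AUV cell. Group 2 held 18 of 36 PL cells (50%, 32.9 to 67.1%), 2 FL cells and 1 each of AUV and YS. Clustering without these groups gave 6 clusters, of which one held 26 of 31 FL cells and no other cell. With 8 principal components 2 clusters held 12 of 31 FL cells each (38.7%), one with no other cell and one with 7 of 36 PL cells (19.4%), 4 YS cells and 2 AUV cells. Such a cluster of a single library set may be that set and not a type.

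**Figure D5:**
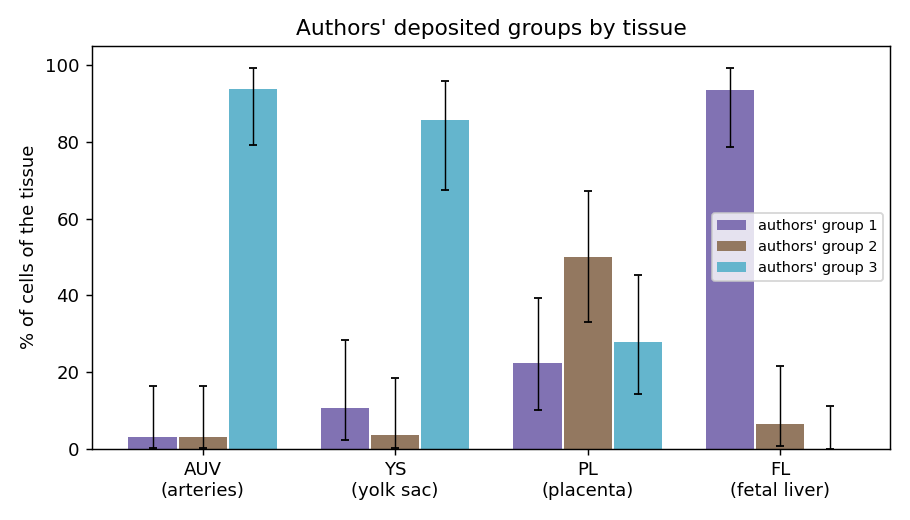
Share of the cells of each tissue in each of the authors' 3 deposited groups; bars are percentages of the tissue's cells and lines exact binomial 95% intervals. Group 3 holds 93.8% of AUV and 85.7% of YS cells, group 1 holds 93.5% of FL cells, and PL is divided as 22.2%, 50% and 27.8%.

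Levels were also compared within these groups. Within group 3, with 30 AUV and 24 YS cells, stem and progenitor genes were higher in AUV in 16 of 21 cases (median 0.74), S phase genes in 14 of 18 (0.41) and endothelial genes in 11 of 15 (0.77, against -0.0046 over the whole tissues), and G2/M genes were higher in YS in 13 of 18 (-0.31, or -0.20 and inside the random range after thinning). Erythroid (1.68), glycolysis (0.33), basement membrane (1.56) and macrophage (-0.44) genes lay outside the random range there as well, the last not after thinning (-0.19). Cholesterol synthesis (-0.22) and venous and lymphatic genes (-0.22) were inside it. The rule again named Zfp260, Serpina3g, Pak1, Hoxa9 and Phkb, with Sla at 164 and 43.8 CPM. In YS it named Zfp777, Rab5a, Slc33a1, G6pdx, Ints12 and Dhx16. Within group 1, all 11 measured megakaryocyte genes were higher in the 8 PL cells than in the 29 FL cells (median 5.48). Several of the 8 stood apart as libraries. PL cells 13 and 14 had 4856 and 3596 genes, and PL cells 17 and 18 had mitochondrial shares of 14.9% and 17.6%. In PL cell 16 that share was 0.0556%, against a PL median of 2.71%. The AUV cell with 69.3% mitochondrial counts is in group 1 too. Library quality and tissue were not separated within this group. PL cell 11 is among the 8 as well. Without it 4 of 6 measured genes were higher, at a median of 2.37, and thinning, which also leaves it out, gave 1.43. The same cells differed in interferon and antigen presentation genes (2 of 19 higher in PL, median -2.09, or -1.93 without PL cell 11). Stem and progenitor genes had a median of -1.04, inside the random range with summed counts (-0.97), and foetal stem programme genes one of 1.46. G2/M genes lay inside the random range (11 of 18 higher in PL, median 0.34), as did glycolysis (-0.37), erythroid (-0.032, or -1.11 without PL cell 11) and visceral endoderm and hepatic genes (-2.42). Outside it here, but not in the whole tissues, were basement membrane (3.15, or 2.23 without PL cell 11), endothelial (0.92) and adhesion and homing genes (-1.45), the last 2 inside it without PL cell 11 (0.30 and -1.33). After thinning, which also leaves out PL cell 11, the endothelial median was 1.23 and outside the random range. S phase genes had a median of -0.72 (2 of 18), which without PL cell 11 was -0.53, inside the random range. Trp53, the tumour suppressor p53 gene, averaged 211 CPM in PL (108 without PL cell 15) and 1221 in FL, and the thymidylate kinase gene Dtymk 28.9 (4.75 without PL cell 12) and 484 CPM. Kdr, the VEGF receptor gene of endothelium, averaged 1305 and 1.06 CPM, or 805 without PL cell 14 and 0.17 without FL cell 11, with a read in 6 of 8 PL and 8 of 29 FL cells. Within group 3, the 24 YS and 10 PL cells differed in dissociation stress genes (12 of 15 higher in YS, median 1.12), in granulocyte and monocyte genes (0 of 6, median -1.01) and in erythroid genes (2 of 8, median -1.21). Regulators of haematopoiesis (0.47) and interferon and antigen presentation genes (-0.37) lay outside the random range too, but not after thinning (0.35 and -0.16). Megakaryocyte (3 of 8 higher in YS, median -0.55), stem and progenitor (0.017), macrophage (0.54) and basement membrane genes (0.38), outside the random range in the whole tissues, were inside it. How the authors made the groups is not given in the sources used here, so they may not separate a mix of types from a difference within one.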

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

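The table holds sequences that belong to no mouse gene, and 5 of the spike-in control sequences had more than the 3 counts that a count of 0 allows. ERCC-00104 had 14750 counts over the 127 cells and a read in every cell. Scaled like CPM, it averaged 70.7 in AUV, 77.8 in YS, 44.2 in PL and 42.4 in FL. The other 4 were far lower over all cells, at 33 counts for ERCC-00060, 7 for ERCC-00123, 6 for ERCC-00083 and 5 for ERCC-00075. The labels do not say whether spike-in controls were added, and no explanation was tested.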

How the results depend on the processing

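Leaving out 6 cells with an outlying mitochondrial share, leaving out each cell in turn, leaving out the cell too shallow to thin, leaving out the cell with most of a gene and random lists drawn under each alternative were chosen after seeing the data. No paired analysis was possible because the result comes from no test and cells of different tissues share no embryo in the labels. Of the 30 list medians outside the random range, 10 stayed outside it on the same side without each cell and under each alternative for which random lists were drawn (all but no floor on members): stem and progenitor, S phase and basement membrane genes in AUV with YS, megakaryocyte, G2/M and interferon genes in PL with FL, erythroid and interferon genes in AUV with FL, and erythroid and megakaryocyte genes in YS with PL. That count is of whole tissues: within the authors' groups, G2/M genes in PL with FL (0.34) and megakaryocyte genes in YS with PL (-0.55) lay inside the range. For whole tissues, medians with each cell left out in turn were set against the random range drawn with all cells. That range was not drawn anew, so calls near its edge are uncertain. Trimmed means put 11 of 29 inside the range, summed counts 9 of 29, members of at least 10 CPM 4 of 28, thinning 3 of 30, scran size factors 3 of 30, the stricter filter 2 of 30, a pseudocount of 5 CPM 2 of 30, leaving out the 6 cells 2 of 29 and the reduced denominator 0 of 30. The main cell filter removed 0 cells, so lifting it moved nothing. For each case below, the cause was not tested unless stated.
Trimmed means moved the G2/M median to 1.65 (PL with FL) and 1.48 (AUV with FL) and the megakaryocyte median to -1.5 (YS with PL). They turned the endothelial (1.80) and venous and lymphatic (0.76) medians of AUV with FL and the basement membrane median of YS with PL (1.22). These 3 lay inside the trimmed random range, and trimming moved the median of all genes to 0.72 in AUV with FL and 0.37 in YS with PL. Summed counts gave 0.25 for G2/M genes in AUV with FL. Members of at least 10 CPM turned the macrophage median of AUV with YS to 0.25. Leaving out each cell in turn gave ranges of -0.70 to 0.018 for that list, -3.13 to 1.24 for erythroid genes in PL with FL, and, in AUV with FL, -1.03 to 0.71 for endothelial and -2.19 to 0.34 for venous and lymphatic genes. Within the authors' group 1, the megakaryocyte median was 1.43 after thinning and 2.37 without the placental cell that thinning leaves out.
Shares of cells moved with depth and threshold. At 10 CPM, Cdh5 was found in 59.4% of AUV, 35.7% of YS, 13.9% of PL and 9.68% of FL cells, and Cdh5 with Ptprc in 59.4%, 17.9%, 8.33% and 6.45%. Thinned, Cdh5 was found in 59.4% of AUV, 20% of PL and 6.45% of FL cells, and Cdh5 with Ptprc in 59.4%, 21.4%, 8.57% and 3.23% of AUV, YS, PL and FL. Ly6a reached 10 CPM in 6.25% of AUV cells. Itga2b reached it in 12.5% of AUV and 7.14% of YS cells, and after thinning had a read in 9.38% of AUV, 7.14% of YS and 5.71% of PL cells. The cluster with most FL cells held 17.9% of YS, 19.4% of PL and 96.8% of FL cells at resolution 0.5, and, with 8 principal components, one of 2 clusters with 12 FL cells each held 14.3%, 19.4% and 38.7%, and the other no cell of another tissue. For named genes, 618 values under alternatives lay outside the counting interval of the log2 ratio, 438 lay within it, and 0 changed sign. These genes were named from the same cells for log2 ratios of at least 1, so few sign changes could arise. The visceral endoderm and hepatic median of PL with FL had too few members for summed counts, trimmed means, members of at least 10 CPM or without the 6 cells, and the venous and lymphatic median of AUV with FL for members of at least 10 CPM. Depth limits what low genes show: a gene near 1 CPM has about 2 counts in a cell of median depth.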

Other observations

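The tests and means without the highest cell and the test of a general shift were chosen only after the results were seen. The lymphoid list lay inside the random range in all 4 comparisons (percentiles 88.9, 60.2, 59.3 and 12.5), while single members had different levels among the tissues. Flt3, a cytokine receptor gene of multipotent and lymphoid progenitors, averaged 89.1 CPM in AUV, 43.9 in YS, 37.4 in PL and 14 in FL. Il7r, the interleukin 7 receptor gene, averaged 41.1, 7.86, 26.8 and 0.16 CPM, with 2.86 in YS without YS cell 10, 10.0 in PL without PL cell 5 and 0.10 in FL without FL cell 4. Il2rg went the other way, at 118, 151, 133 and 368 CPM. Among adhesion and homing genes, Selplg averaged 35.4 CPM in AUV, 12.6 in YS, 11.7 in PL and 130 in FL (6.33 without YS cell 21 and 6.97 without PL cell 9), and Cd93 669, 487, 558 and 1327 CPM. The list was at 0.42 in AUV with YS (10 of 12 higher in AUV, percentile 97.4), inside the range. Arterial genes were at 0.60 there (9 of 11 higher in AUV), also inside it. The heat shock genes Hspa1a and Hspa1b averaged 67.9 and 46.8 CPM in AUV, against 7.21 and 5.11 CPM in YS, where Hspa1b averaged 0.96 CPM without YS cell 17.

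Cells with both Xist and the Y-linked sum at 10 CPM numbered 17 of 32 in AUV (53.1%, 34.7 to 70.9%), 8 of 28 in YS, 4 of 36 in PL and 4 of 31 in FL. Cells with neither numbered 0, 4, 9 and 7. No explanation was tested.

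The megakaryocyte list was higher in placenta than in fetal liver. RNA shared by all cells of the suspension would spread over them, but the 5 PL cells with most held 96.3% of the summed CPM, and 93.4% without the highest cell. The 2 cells with most held 53.3% and 35%, so without the first the second set that share. The share without both was not computed. These values therefore speak only to the levels in those 2 cells, and shared RNA in the other PL cells stays open. The highest cell, with 53.3% of the sum, was also the shallowest of all cells (73786 counts). Thinning left it out, and without it the median was 3.94 before thinning (with the filter of 200000 counts) and 3.84 after. Since thinning leaves the expected mean CPM of a gene unchanged, these values cannot decide on depth. Depth, doublets, the quality of the shallowest library, the LSK-SLAM gate of the FL cells and a tissue difference stay open. The hypothesis that a few placental cells carried a megakaryocyte programme rests mainly on 2 cells.

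The G2/M list was higher in placenta than in fetal liver. After thinning its median was 0.81, against 0.76 before. Thinning leaves the expected mean CPM of a gene unchanged, so these values cannot decide on depth. The median of all genes was -0.095, and from -0.13 to 0.16 over the alternatives. CPM gives every cell the same total, and the list was picked for lying outside random lists of the same genes. These values therefore cannot decide on a general shift. Within the authors' group 1, with 8 PL and 29 FL cells, the list was at 0.34 and inside the random range. Several of those 8 cells stood apart as libraries, so that value may not describe placental cells in general. Depth, a general shift, library quality, a different mix of cells, the LSK-SLAM gate and the tissue stay open as candidate sources and were not separated.

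Adult-type globin reads were found in 29 of 31 FL cells (93.5%, 78.6 to 99.2%). Erythroid cells among the sorted cells would also carry other erythroid genes. Of Gypa, Alas2, Slc4a1, Ermap and Klf1 none had a read in more than 22.6% of FL cells (9.59 to 41.1%). The globin share counts cells with either of 2 genes, whereas these 5 were counted singly, and the share with any of them was not computed. Car2, also on the erythroid list, had a read in 29 of 29 FL cells of group 1, at 2044 CPM (1597 without FL cell 1). Erythroid cells as the source therefore stay open. Free RNA shared by the suspension cannot be told apart from expression. The 5 cells with most held 90.5% of the summed CPM, beyond the 80% set beforehand as evidence against sharing, but that bound overlooked a single cell, which held 78.5%, and without it the next 5 held 64.7%, under the bound.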
